A study of Mus musculus with 6 samples.

How the data were processed

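Gene expression was measured on 6 oligonucleotide arrays of 45101 probe sets, each hybridised with amplified total RNA of mouse embryonic stem cells. Per the labels' protocols, cells were seeded at 50000, grown for 4 days in stem cell medium lacking the self-renewal cytokine LIF and holding 10 µM retinoic acid, then stained for the surface antigen SSEA1 and sorted. Also per the labels, RNA was extracted with a micro-scale column kit and amplified with a whole-transcriptome kit made for degraded RNA, which yields cDNA that was then labelled with biotin. The labels place 3 samples in the wild type group and 3 in the Pten-/- group, numbered 1 to 3 as biological replicates. They do not say how many stem cell lines of each genotype were used, so the p-values measure the spread between these samples.

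The deposited values are intensity values, 1 linear signal per probe set and array, made by the authors with MAS5, per the submitters' processing notes. The software version and the scaling target are not given in the sources used here. In the deposited values, the mean after trimming 2% of probe sets at each end was 500.0 on each array, so each array had been scaled as a whole to the same trimmed mean. Detection calls and scanner files were not used here. MAS5 takes the mismatch probe of each pair into account, which leaves low signals with large relative errors, and a global scaling hides any change in total RNA per cell.

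The 64 control probe sets were set aside. Of the other probe sets, 34945 had 1 gene symbol in the platform annotation, 932 had several and 9160 were unlisted and are unnamed here. No symbol changed when the annotation was updated through gene identifiers against the RefSeq genes of GRCm38.p6, and 204 identifiers had no match there and kept their symbol. The array coordinates were not used here, and the RefSeq table served only for names and for which genes overlap. Signals were transformed as log2(signal + 23.6), where the pseudocount is the 25th percentile of all signals. Fold changes are therefore on the log2(signal + pseudocount) scale and understate the change of genes with low signal. Each of the 18193 named genes was represented by its probe set with the highest mean log2 value. Genes were tested if that mean reached the median of all probe sets, equal to a signal of 109, which left 11082 genes.

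Pten-/- and wild type arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend of the variance on mean signal), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The replicate number did not enter the fit. The gene lists, 30 in number with 629 distinct genes, were written from textbook knowledge before the data were examined, as were the tests, the named-gene rule and all alternatives except those named as added later. Of the list genes, 579 were named on the array and 493 were tested. The 27 lists with at least 5 tested genes were compared with all other genes by limma's camera with a preset correlation of 0.01 between genes, and again with a correlation estimated from the data. Each list was also tested with limma's fry, which asks whether its genes move one way on balance and, separately, whether they change in either direction. The named genes were Pten, then Nanog, Pou5f1, Sox2, Klf4, Esrrb, Zfp42, Fut4 and Fut9 whatever their result, then genes past the threshold whose groups did not overlap (up to 12 each way). Where fewer than 5 genes passed in a direction, the next 5 by p were added as values. In each list, up to 4 members past the threshold were named, or else the 2 with the smallest p. List members below the signal filter were only counted.

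The fit was tested on simulated data with the measured means and spreads of the 11082 genes of this comparison, with 200 genes changed in each of 20 simulations. It recovered 3.3% of genes changed by 0.5 on the log2 scale, 50.6% of those changed by 1, 99.3% of those changed by 2 and 99.9% of those changed by 3, and 7.02% of its calls were false. These shares hold with 200 genes changed at once, which loosens the adjusted threshold. In the data 2 genes passed, and Igf2r with an unadjusted p of 1.8e-05 in limma's test did not. The shares recovered there would therefore be lower. In simulations with no gene changed, the fit called 0.45 genes on average. A list of 20 genes shifted by 0.4 was found by camera in 20 of 20 simulations and an unshifted list in 1 of 20. The simulated genes varied independently of each other, so these list results do not cover correlated genes. For arrays, the number of arrays limits the precision. With 3 against 3, an exact permutation test of a single value cannot give a two-sided p below 0.1, so values are compared through limma's fit.

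The alternatives were other pseudocounts, no filter and a stricter filter, quantile normalisation, centring each array on its median, no variance trend, array weights, the mean of a gene's probe sets, a preference for probe sets without a cross-hybridisation suffix, all probe sets tested separately, the replicate number as a block, an adjusted threshold of 0.1, a minimum log2 fold change of 1 and each array left out in turn. A covariate made from the Cre hybridisation controls, fry on the imprinted list without Grb10 and Igf2r and on the Nodal and BMP list without Lefty1 and Lefty2, the separation of list means and 1 other split of the arrays after quantile normalisation and after centring, and the count of imprinted genes among the smallest p, were added after seeing the data. Figures were drawn with matplotlib 3.10.9.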

Results

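The transcriptome of SSEA1-positive cells was compared between wild type and Pten-/- mouse embryonic stem cells after 4 days of differentiation with 10 µM retinoic acid. SSEA1 is a surface glycan of undifferentiated mouse embryonic stem cells, so the sort kept cells that still carried it under a treatment that drives most cells to differentiate. Pten is the lipid phosphatase that opposes PI3K signalling. The series design states that such sorted cells formed tumours after transplantation into immunodeficient mice when they lacked Pten and did not when they were wild type, and the arrays asked how the sorted cells differ. Each genotype had 3 arrays. Across the 11082 genes tested, the correlation of log2 signals was between 0.904 and 0.972 for arrays of the same genotype and between 0.923 and 0.969 for arrays of different genotypes. The ratio of 3' to 5' signal of the Gapdh control was between 1.41 and 1.502 on wild type arrays and between 1.37 and 1.68 on Pten-/- arrays. That of the Actb control was between 1.07 and 1.16 on wild type arrays and between 1.03 and 1.2 on Pten-/- arrays. As the amplification was made for degraded RNA, these ratios are only a loose sign of RNA length. The level of Pten was not analysed here, because no probe set used carried that name, and the genotypes rest on the labels.

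Grb10, an imprinted adaptor protein that binds the insulin and IGF1 receptors and dampens their signalling, fell 8.48-fold in Pten-/- cells. Its signal was 8553 ± 1139.7 in wild type and 998 ± 220.2 in Pten-/- (SD, n = 3 each), a log2 fold change of -3.08 ± 0.20 (SE, adjusted p = 0.000334). The other 2 probe sets of Grb10 gave -3.40 and -3.56. LOC102631979, a long noncoding RNA gene that overlaps Grb10 in GRCm38.p6, fell from a signal of 579 ± 202 to 41.7 ± 10.9 (SD, n = 3 each), with a log2 fold change of -3.16 ± 0.32 (SE, adjusted p = 0.00899). The lower signal lay near the pseudocount of 23.6, and this value was -3.73 with a pseudocount of 1 and -2.13 with one at the 50th percentile, so its size is loosely set. For these overlapping genes the array annotation does not settle which transcript each probe set reads. All 3 Pten-/- arrays lay below all 3 wild type arrays for both genes.

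These were the only genes past the adjusted threshold in limma's test, 2 lower and 0 higher in Pten-/-. At an unadjusted p under 0.05 there were 337 genes, 134 higher and 203 lower, where 554 would be expected by chance. The groups did not overlap for 919 genes, 8.29% of those tested, and chance gives 10%. Without wild type replicate 1 or wild type replicate 3, LOC102631979 missed the threshold (adjusted p = 0.167 and 0.104), and the count fell from 2 to 1. With array weights 6 genes passed, and without Pten-/- replicate 3 the count was 3.

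The next genes by p among those with lower signal in Pten-/- did not pass. Igf2r, the receptor that takes up IGF2 for degradation and also an imprinted gene, had a log2 fold change of -1.34 ± 0.18 (SE, adjusted p = 0.0666), with signals of 2903 ± 275 in wild type and 1134 ± 100.2 in Pten-/- (SD, n = 3 each). Asb4, which encodes an ankyrin repeat protein with a SOCS box, had -2.07 ± 0.34 (SE, adjusted p = 0.297). Array weights took Igf2r, Asb4, Lefty1 and Lefty2 past the threshold, and averaging the probe sets took Asb4 past it. For Lefty1, Lefty2 and H13 the adjusted p was 0.999. Lefty1 and Lefty2, secreted inhibitors and targets of Nodal signalling, had log2 fold changes of -1.07 ± 0.24 and -1.14 ± 0.28 (SE). H13, the gene of signal peptide peptidase, had -0.96 ± 0.22 (SE) on its brightest probe set, and its other probe sets past the filter gave values of 0.05, -0.15 and 0.19. Among genes with higher signal in Pten-/-, the smallest p belonged to Btbd19 with 1.24 ± 0.27, Shisa4 with 0.84 ± 0.19, the Y-linked gene Uba1y with 1.22 ± 0.28, the IGF-binding protein gene Igfbp6 with 1.06 ± 0.25 and the metalloproteinase gene Mmp23 with 1.06 ± 0.27 (log2 fold change ± SE). Each of these had an adjusted p of 0.999 and, on the probe set used, higher signal on all 3 Pten-/- arrays than on any wild type array. The other probe sets of Btbd19 and Mmp23 past the filter gave -0.03 and 0.43, with overlapping arrays.

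**Figure D1:**
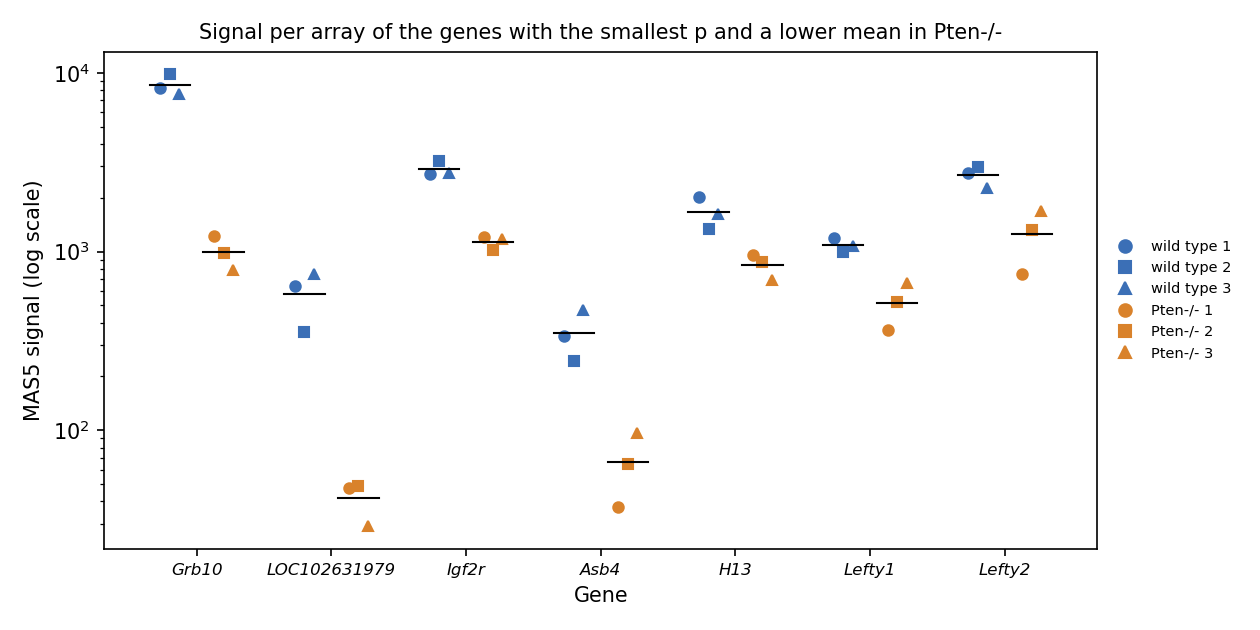
MAS5 signal on a log axis for each array, for the 2 genes past the threshold and the 5 genes that follow them by p among those with lower signal in Pten-/-. Points are arrays (marker shape is the replicate number, blue wild type, orange Pten-/-) and black lines are group means (n = 3), and for Grb10 the means are 8553 and 998.

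The core pluripotency regulators did not pass the test. Pou5f1 had a log2 fold change of -0.25 ± 0.43, Nanog -0.47 ± 0.35, Sox2 -0.89 ± 0.35, Esrrb -0.63 ± 0.31, Zfp42 -0.44 ± 0.18 and Klf4 0.49 ± 0.23 (SE, adjusted p = 0.999 each). Sox2 and Zfp42 were lower, and Klf4 higher, on all 3 Pten-/- arrays than on any wild type array, while the arrays overlapped for the others. The other probe set of Klf4 past the filter, about as bright, gave -0.17 with overlapping arrays. Pou5f1 signals were 336, 950.0 and 235 on Pten-/- replicates 1 to 3 against 397 to 673 in wild type, and its log2 fold change was -0.81 without Pten-/- replicate 2 and 0.15 without Pten-/- replicate 3. That of Nanog was -0.85 without Pten-/- replicate 2 and -0.06 without Pten-/- replicate 1. For Sox2 the smallest fall among the alternatives was -0.47, without Pten-/- replicate 1, whose signal was 185 against 506 and 445 on the other Pten-/- arrays. Fut4, a fucosyltransferase that can make the SSEA1 epitope, had -0.02 ± 0.28, and Fut9, the enzyme that makes SSEA1 in early mouse embryos, lay below the signal filter on its 3 probe sets.

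As a group, the 24 tested pluripotency genes were lower in Pten-/-, with a mean log2 fold change of -0.39, 21 members negative and 3 positive. Camera gave an adjusted p = 1.1e-05, and the adjusted p = 0.371 with an estimated correlation. Of these genes 0 passed over all genes and 0 adjusted over the list alone. Dppa2 with -0.63 ± 0.16 and Fbxo15 with -1.03 ± 0.35 (SE) had the smallest p. The per-array mean of the list overlapped, since Pten-/- replicate 2 lay at 0.28 and the wild type arrays between 0.06 and 0.41 relative to the mean of all arrays. Of the other Pten-/- arrays, replicate 1 at -0.37 was the array with the highest extraembryonic endoderm mean, 1.004, and the highest epithelial junction mean, 0.47, and replicate 3 at -0.49 had the highest Gapdh 3' to 5' ratio, 1.68. The primed epiblast list, genes of the state that follows naive pluripotency, was lower by a mean log2 of -0.50, with 11 of 12 members negative (camera adjusted p = 8.33e-06, adjusted p = 0.154 with an estimated correlation). Adjusted over the list alone, 3 members fell and 9 did not pass, while 0 passed over all genes. These were Lefty1, Lefty2 and Fgf5, the last with -1.21 ± 0.30 (SE) and named after its value was seen. This list's mean separated the arrays, with wild type between 0.22 and 0.29 and Pten-/- between -0.36 and -0.18.

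Targets of Nodal and BMP signalling were lower by a mean log2 of -0.29, with 10 of 14 members negative (camera adjusted p = 0.0184, adjusted p = 0.359 with an estimated correlation). Lefty1 and Lefty2 are on this list too and were the 2 members that fell adjusted over the list alone, against 0 over all genes. Targets of ERK signalling were lower by a mean log2 of -0.23, with 11 of 13 negative (camera adjusted p = 0.0155, adjusted p = 0.371 with an estimated correlation) and 0 members past either adjustment. The per-array means of both lists separated the genotypes, for Nodal and BMP targets with wild type between 0.09 and 0.20 and Pten-/- between -0.19 and -0.07, and for ERK targets with 0.06 to 0.17 against -0.30 to 0.03, though for ERK not after centring each array on its median. The phosphatase gene Dusp6 had -0.56 ± 0.18 and the transcription factor gene Etv5 -0.62 ± 0.24 (SE), although the other probe sets of Etv5 gave -0.07 and -0.30. Without Pten-/- replicate 2 the ERK mean was -0.14.

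The list of chromatin and DNA methylation genes was lower by a mean log2 of -0.19, with 20 of 24 members negative (camera adjusted p = 0.00288, adjusted p = 0.371 with an estimated correlation). Hells, a chromatin remodeller needed for DNA methylation, had -0.44 ± 0.19, and Ezh2, the histone H3 methyltransferase of Polycomb, had -0.36 ± 0.17 (SE). Cell cycle genes were lower by a mean log2 of -0.12, with 22 of 31 negative (camera adjusted p = 0.0467, adjusted p = 0.371 with an estimated correlation), among them Mycn with -0.86 ± 0.30 and the replication helicase subunit Mcm7 with -0.40 ± 0.15 (SE). The p53 targets and apoptosis list was higher by a mean log2 of 0.18, with 21 of 23 members positive (camera adjusted p = 0.000512, adjusted p = 0.307 with an estimated correlation). Cdkn1a, the cell cycle inhibitor p21, had 0.51 ± 0.23 and the antiproliferative gene Btg2 0.36 ± 0.19 (SE). Other probe sets past the filter gave smaller values for Hells with -0.05 and -0.04, Mycn with -0.27 and Cdkn1a with 0.10, and without Pten-/- replicate 3 the cell cycle mean was -0.07. The per-array means separated the genotypes for chromatin genes, with wild type between 0.01 and 0.17 and Pten-/- between -0.17 and -0.03, and for cell cycle genes, with 0.04 to 0.10 against -0.16 to 0.01, but for neither after centring. Those of the p53 list overlapped, with Pten-/- replicate 3 at -0.03 and wild type replicate 3 at -0.01, and separated after centring. In each of these 3 lists 0 members passed over all genes and 0 adjusted over the list alone.

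Genes of other lineages were uneven between replicates. Extraembryonic endoderm genes were higher in Pten-/- by a mean log2 of 0.34, with 18 of 22 members positive (camera adjusted p = 0.00311, adjusted p = 0.732 with an estimated correlation). That rested on Pten-/- replicate 1, whose list mean lay at 1.004 while the other 5 arrays lay between -0.35 and -0.06, and without it the mean log2 fold change was -0.08, against 0.55 and 0.54 without Pten-/- replicates 2 and 3. Ttr, the thyroid hormone carrier transthyretin, had 1.66 ± 0.74 and the endoderm transcription factor Foxa2 0.96 ± 0.54 (SE). Neural lineage genes were lower by a mean log2 of -0.28, with 12 of 14 negative (camera adjusted p = 0.0486, adjusted p = 0.817 with an estimated correlation). Sox1, a marker of neural precursors, had -0.92 ± 0.44 and Stmn2 -0.84 ± 0.42 (SE). The neural list means of wild type replicates 1 and 3 and Pten-/- replicate 3 lay at 0.13, 0.51 and 0.51. Those of wild type replicate 2 and Pten-/- replicates 1 and 2 lay at -0.22, -0.56 and -0.36. The neural means therefore followed a split of the arrays other than genotype, and the mean fall cannot be told apart from that split. The neural mean was -0.60 without Pten-/- replicate 3, -0.46 without wild type replicate 2, -0.17 without Pten-/- replicate 2, -0.09 without wild type replicate 3 and -0.07 without Pten-/- replicate 1. In both lists 0 members passed over all genes and 0 adjusted over the list alone.

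The retinoic acid response did not differ past the threshold. Its 21 tested genes had a mean log2 fold change of 0.05 and a median of -0.00014 (camera adjusted p = 0.625), with Hoxb1 at -0.50 ± 0.21 and Tgm2 at 0.51 ± 0.26 (SE). The 21 Hox genes tested had a mean of -0.14 (adjusted p = 0.135), with Hoxd8 at -0.65 ± 0.23 and Hoxc4 at -0.50 ± 0.19. Germ cell genes (mean -0.07, adjusted p = 0.699, Prdm1 0.63 ± 0.33 and Piwil2 -0.48 ± 0.29), mesoderm genes (mean -0.15, adjusted p = 0.452, Kdr -0.98 ± 0.43 and Bmp4 -0.41 ± 0.24) and trophectoderm genes (mean 0.14, adjusted p = 0.203, Gata3 0.93 ± 0.38 and Bmp4 again) did not pass. Nor did Wnt targets, with a mean of -0.18 (adjusted p = 0.469, Lef1 -0.44 ± 0.27 and Axin2 -0.58 ± 0.39). Without Pten-/- replicate 2 the value of Axin2 was -0.07, and its other probe set gave -0.57 on all arrays, with overlapping groups.

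Genes tied to the pathway that Pten restrains did not pass as groups either. The 27 PI3K pathway components had a mean log2 fold change of -0.03 (camera adjusted p = 0.954). Pik3r3, a regulatory subunit of PI3K, had 1.15 ± 0.34 and Inpp5d, the inositol phosphatase SHIP1, had 0.78 ± 0.25 (SE), with all 3 Pten-/- arrays above the wild type arrays for each. FoxO targets, genes that AKT represses, had a mean of -0.13 (adjusted p = 0.164), with Insr at -0.56 ± 0.28 and Klf2 at -0.51 ± 0.30. Sterol and lipid synthesis genes had a mean of 0.08 (adjusted p = 0.135), with Insig1 at 0.62 ± 0.35 and Fdft1 at 0.35 ± 0.21, and genes of mitochondrial respiration had 0.06 (adjusted p = 0.0965), with Ndufs3 at 0.36 ± 0.19 and Ndufs1 at 0.25 ± 0.19. Glycolysis and hypoxia genes had a mean of -0.02 (adjusted p = 0.954), with Pdk1 at -0.16 ± 0.20 and Pfkl at -0.17 ± 0.22. The per-array means of these genes ran from -0.51 on Pten-/- replicate 3 to 0.41 on wild type replicate 2, with an estimated correlation of 0.83. A mean near 0 therefore says little about genotype there. Ribosomal protein genes had a mean of -0.01 (adjusted p = 0.954), with Rps19 at 0.23 ± 0.26 and Rpl11 at -0.14 ± 0.23. Camera's direction was up for both of these lists although their means were below 0, where the median of all genes was -0.03.

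The 21 imprinted genes of the list fixed beforehand moved in both directions, with a mean log2 fold change of -0.13, a median of 0.02 and an adjusted p = 0.897 from camera. Over all genes 1 of them passed, Grb10. Adjusted over the list alone, Grb10 and Igf2r fell and Impact, named after its value was seen, rose with 0.76 ± 0.20 (SE). Limma's fry, which here asked whether list members changed in either direction, gave this list an adjusted p = 4.67e-05, and without Grb10 and Igf2r the adjusted p was 0.944. The other list past this either-direction test was that of Nodal and BMP targets with an adjusted p = 0.00912, and without Lefty1 and Lefty2 the adjusted p was 0.222. Both settings without leading genes were added after seeing the data.

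Other lists of cells or states that a sort could hold did not pass, unlike the extraembryonic endoderm and neural lists. Fibroblast genes, which feeder cells would bring, had a mean of 0.03 (adjusted p = 0.497), with Col1a2 at -0.36 ± 0.16 and Thy1 at -0.82 ± 0.54 (-0.05 without Pten-/- replicate 3). Epithelial junction genes had 0.12 (adjusted p = 0.164), with Cldn4 at 0.75 ± 0.35 and Crb3 at 0.76 ± 0.42 (0.04 and -0.15 on its other probe sets), and mesenchymal transition genes had -0.09 (adjusted p = 0.783), with Itgb3 at -0.58 ± 0.47 and Cdh2 at -0.49 ± 0.47. Genes of the dissociation stress response had -0.06, a median of 0.01 and a camera direction of up (adjusted p = 0.783), with Hspa1a at -1.19 ± 0.40 and Btg2 as above. Genes of SSEA1 glycan synthesis had a mean of 0.0014 and a median of -0.06 (adjusted p = 0.783), with St3gal6 at 0.42 ± 0.24 and B4galt3 at 0.29 ± 0.24. Blood and endothelium, 2-cell-like and sex chromosome lists each had 4 tested genes, too few for a list test, and 0 of them passed. Among these, Fli1 had -0.70 ± 0.37, Zfp352 -0.92 ± 0.42, Usp17la -0.95 ± 0.54, Eif2s3y 0.41 ± 0.17 and Sry -0.44 ± 0.37 (log2 fold change ± SE). Without Pten-/- replicate 3 the value of Usp17la was -0.16.

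**Figure D2:**
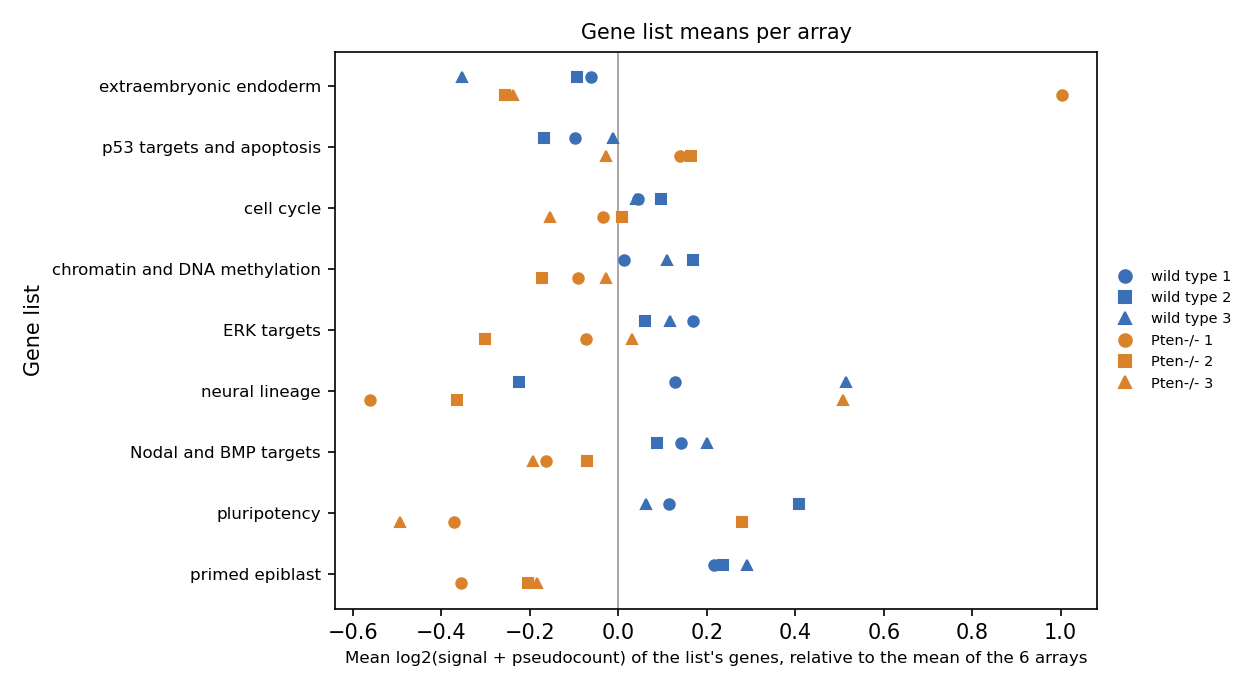
Mean log2(signal + pseudocount) of the tested genes of each list past camera's threshold, per array, relative to the mean of the 6 arrays. Points are arrays (marker shape is the replicate number, blue wild type, orange Pten-/-), and the means of the primed epiblast, Nodal and BMP, ERK, chromatin and cell cycle lists separate the genotypes (the last 3 not after centring each array on its median), while those of the others overlap and the extraembryonic endoderm list is set apart by Pten-/- replicate 1 at 1.004.

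Of the 27 lists tested, 9 passed camera's threshold, 2 higher and 7 lower in Pten-/-, and 0 passed with an estimated correlation, while fry gave 1 list that moved one way on balance, the primed epiblast list (adjusted p = 0.0105), and 2 that changed in either direction, the imprinted and the Nodal and BMP lists. The per-array means of 7 lists, 25.9%, separated the genotypes, where chance gives 10% for a single list, and those of 6 did after quantile normalisation and 3 after centring each array on its median. The 7 were the primed epiblast, Nodal and BMP, ERK, chromatin, cell cycle, Wnt and FoxO lists, and after centring the 3 were the primed epiblast, Nodal and BMP and p53 lists. The primed epiblast, pluripotency and p53 lists kept their call whichever array was left out, but the pluripotency mean moved from -0.39 to -0.63 without Pten-/- replicate 2 and to -0.24 without Pten-/- replicate 3. Without Pten-/- replicate 1 the chromatin, Nodal and BMP, ERK, cell cycle, neural and extraembryonic endoderm lists lost theirs (adjusted p = 0.0519, 0.0519, 0.0715, 0.181, 0.842 and 0.747). Nodal and BMP targets also missed it without wild type replicate 3 (0.0749), ERK targets without wild type replicate 1 or Pten-/- replicate 2 (0.101 and 0.281), and neural genes without wild type replicate 1, wild type replicate 3 or Pten-/- replicate 2 (0.0743, 0.719 and 0.295). Cell cycle genes kept it only without Pten-/- replicate 2 among the arrays left out, with adjusted p between 0.0586 and 0.206 for the others.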

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

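Grb10 stayed past the threshold in all 20 alternatives, with log2 fold changes between -3.35 and -2.85 and adjusted p between 1.44e-05 and 0.00854. LOC102631979 passed in 17 of 19 (adjusted p between 0.000221 and 0.167), and the stricter filter removed it, so the count of genes was 1 there. Array weights gave 6 genes, and leaving out 1 array at a time gave between 1 and 3, of which Ptgds, 2.21 higher on the log2 scale without Pten-/- replicate 3, was the only one higher in Pten-/-. Leaving out an array leaves fewer samples, and the cause of the other moves was not tested. The count of lists was 9 and became 0 with a correlation estimated from the data and 1 with fry, and it ran between 4 (without Pten-/- replicate 1) and 14 (without wild type replicate 2). With an estimated correlation, camera's smallest adjusted p was 0.154, for the primed epiblast list, and it was 0.359 for Nodal and BMP targets. The estimated correlations of these 2 lists were -0.043 and -0.041, below the preset 0.01. Correlation between their genes therefore does not account for the loss of their calls. For the primed epiblast list, camera's unadjusted p rose from 3.08e-07 to 0.00571 at this lower correlation. A call lost under this setting is thus not by itself a sign of correlated genes. The other lists past camera's threshold had estimated correlations between 0.014 and 0.565, and how far these account for their lost calls was not tested. The mean of the extraembryonic endoderm list reversed to -0.077 without Pten-/- replicate 1 and was 0.55 without Pten-/- replicate 2. The primed epiblast list passed in 17 of 18 alternatives, pluripotency and p53 in 16, chromatin and extraembryonic endoderm in 15, Nodal and BMP in 14, ERK in 11, cell cycle in 9 and neural in 7. The cell cycle list missed the threshold after centring on the median (adjusted p = 0.0535), and the neural list after that and after quantile normalisation (0.0512 and 0.0511). Of the other named genes' values, 1274 stayed within 1 SD of the main value, 38 moved by more and 5 passed the threshold, 4 of them with array weights. The replicate block gave 2 genes and 9 lists, and it changed no call. Same-numbered arrays did not all deviate together from their group means (r across genes of -0.04, 0.24 and 0.51), and 3 of 6 arrays correlated best with their own number, so the numbers were not read as pairs. The covariate from the Cre controls, chosen after seeing the data, gave 2 genes and 12 lists. No scaling moved the median of all genes by over 0.1. Signals near the pseudocount of 23.6 carry little information, and the fold of LOC102631979, at 41.7 in Pten-/-, ranged from -3.73 with a pseudocount of 1 to -2.13 with one at the 50th percentile.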

Other observations

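The tests of other splits and of their normalisation, of other probe sets, of the spread among pluripotency genes and of Y-linked genes were chosen only after the results were seen, as were the count of imprinted genes among the smallest p and the list of parental alleles, the latter written from textbook knowledge. Genes that are not in the named-gene rule were picked here after their values were seen. Several imprinted genes besides Grb10 stood near the top of the ranking. The maternally expressed genes Igf2r, Asb4 and H13 had negative log2 fold changes, while the paternally expressed genes Impact with 0.76 ± 0.20 (0.35 on its other probe set past the filter) and Sgce with 0.74 ± 0.23 (SE) had positive ones, none past the threshold over all genes. Airn, the noncoding RNA transcribed antisense across Igf2r, had log2 fold changes of 0.60, 1.04, 1.06 and 1.19 on its 4 probe sets past the filter, each higher on all 3 Pten-/- arrays than on any wild type array. Pten-/- replicate 3 was the highest array on those with 1.04, 1.06 and 1.19, though not on that with 0.60. On the probe set with 1.19 its signal was 1870, against 638 and 534 on Pten-/- replicates 1 and 2 and 185 to 512 in wild type. The paternally expressed gene Igf2 had 0.27 ± 0.15 and Peg10, Mest and Peg3 had 0.12 ± 0.15, -0.20 ± 0.19 and -0.13 ± 0.21, and the maternally expressed noncoding RNA Meg3 had 0.08 ± 0.17 (SE).

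Of 2416 unnamed probe sets past the filter, 0 passed limma's adjusted threshold and 33 had an unadjusted p under 0.05. The smallest p belonged to 1448194_a_at, whose signal was 7931 ± 354 in wild type and 2498.5 ± 1538 in Pten-/- (SD, n = 3 each), a log2 fold change of -1.90 ± 0.44 (SE).

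The first component of the 6 arrays held 42.6% of the variance and set Pten-/- replicate 2 at 36.7 against Pten-/- replicate 3 at -34.4. Of the 10 splits of the 6 arrays into 3 and 3, the genotypes gave 337 genes at an unadjusted p under 0.05 in limma's test. The others gave 1415, 1089, 658, 600, 550, 372, 263, 112 and 98. The most, 1415, came from the split of wild type 1, wild type 3 and Pten-/- 3 against the other arrays, which points to a structure of the samples or arrays other than genotype. Those 3 arrays also had the highest median signals, 112, 119 and 140 against 96.3 to 99.8 on the others, and the highest 25th percentiles, 24.4, 25.4 and 32.6 against 20.5 to 20.8. After quantile normalisation the split gave 1422 genes and after centring each array on its median 1428. Some list means, looked at after the split was seen, followed it too. Hox means were 0.17, 0.23 and 0.19 on those 3 arrays, against -0.195, -0.17 and -0.22 on wild type 2, Pten-/- 1 and Pten-/- 2. In the same order, glycolysis and hypoxia means were -0.10, -0.28 and -0.51 against 0.41, 0.10 and 0.39. Neural means followed it as well, while those of other lists, such as ribosomal proteins, overlapped. The split is partly aligned with genotype. Whether it arose in the cells or in the handling of the arrays was not settled. Among the 10 splits of the 6 arrays, 1, the real one, gave as many as 2 genes past the adjusted threshold, the highest of the others gave 0, and 10 splits are too few to give a share under 0.05.

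For the lead of imprinted genes in the ranking, array brightness was tested with the Cre control covariate. With it, the median absolute log2 fold change of Grb10, Igf2r, Asb4 and H13 was 102.5% of its value without it. The Cre signals of the genotypes overlapped, from 25288 to 43350 on wild type arrays and from 27409 to 35080 on Pten-/- arrays. A covariate so alike in both groups could hardly change the fold change, so this test does not decide on array brightness. Probe sets that bind other transcripts are argued against for Igf2r and Asb4. Of their other 2 probe sets past the filter, 100% had a log2 fold change below -1. For Grb10 this stays open although 100% of its other 2 did too, because they could read the overlapping LOC102631979, and the other probe sets of H13 did not follow. The list fixed beforehand does not hold Asb4 or H13, so its counts do not bear on them. Of its 21 members, 3 were among the 20 smallest p, where 0.038 would be expected (one-sided Fisher's exact p = 0.000177 after Bonferroni over the 27 lists). Without Grb10, however, that exact p was 0.484, 0.0156, 0.00252 and 0.0196 among the 10, 20, 50 and 100 smallest. Chance therefore stays open for the members besides Grb10, and the list's median absolute t, at the 88.4th percentile of 10000 random lists matched on mean signal, hardly responds to a few leading members and decides nothing. A candidate explanation is a shift from the maternal to the paternal expression state at some imprinted loci. Among genes whose values had not been seen, the 11 paternally expressed ones lay only 0.143 above the 12 maternally expressed ones in mean log2 fold change (one-sided permutation p = 0.116). A mean over all these genes responds little to a shift at some loci only, so this test leaves the explanation undecided. Whether loss of Pten or the history of a line goes with the change was not tested, since the labels do not say how many stem cell lines stand behind each genotype.

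For the lower level of pluripotency and primed epiblast genes in Pten-/-, array brightness was tested in the same way. The mean log2 fold change of both lists kept 91.1% of its size with the Cre control covariate. This does not decide either, since the Cre signals of the genotypes overlapped. A smaller share of undifferentiated cells may account for the lower level, although the sort on SSEA1 would remove cells that had lost that marker. Beside the pluripotency means, Pten-/- replicate 1 at -0.37 had extraembryonic endoderm at 1.004 and epithelial junction genes at 0.47, while Pten-/- replicate 3 at -0.49 had -0.24 and -0.29 for these lists and the highest Gapdh 3' to 5' ratio, 1.68, and Pten-/- replicate 2 lay at 0.28. The spread of the pluripotency members' log2 fold changes was 1.14 times their median standard error, which neither excludes an even fall nor requires more, so a change within the sorted Pten-/- cells stays open as well.

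The Y-linked genes Uba1y with 1.22 ± 0.28 and Eif2s3y with 0.41 ± 0.17 (log2 fold change ± SE) were higher on all 3 Pten-/- arrays than on any wild type array, and Uty had 0.29 ± 0.29. More cells or copies with a Y chromosome could give such values if all Y-linked genes rose alike, and the lowest of the 4 past the filter, Sry at -0.44 ± 0.37, lay below 0 by less than 2 standard errors and decides nothing.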
